A study of Canis lupus familiaris with 58 samples.

How the data were processed

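Total RNA was extracted with Trizol from tumour tissue taken before treatment, amplified and labelled with a biotin kit and hybridised to Affymetrix canine GeneChips, per the labels' protocols. The authors deposited log2 expression values of 43035 probe sets for 58 arrays, made with Affymetrix Expression Console and RMA, which corrects background, normalizes between arrays and summarises probes, per the submitters' processing notes. No version of these tools, scan date or batch was used here, and the log2 scale was read from the deposited values, which run from 2.82 to 15.11 with 0 missing. Whether all arrays were normalized together is not given in the sources used here; array medians lay between 7.08 and 7.20, and the largest spread of any quantile between arrays was 0.367.

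Each sample came from a different dog, so p-values of the single-gene and permutation tests measure the spread between dogs. No pair of arrays looked like a repeat: the closest pair correlated at 0.989, shared 1 identical value and had a median absolute difference of 0.135. Mean correlation with the other arrays had a median of 0.972 and lowest values of 0.940 and 0.952, both in aspirates. The 3' minus 5' difference of the GAPDH and ACTB control probe sets, a measure of RNA integrity, was 0.31 ± 0.48 (SD, n = 26) in static and 0.36 ± 0.32 (n = 27) in ongoing samples (permutation p = 0.692), and 0.32 ± 0.38 in aspirates and 0.35 ± 0.39 in lymph node (permutation p = 0.863). These means hide 1 static lymph node sample at 2.48 and 1 ongoing aspirate at 1.72, while the next highest value was 0.71. That aspirate was also the array with the lowest mean correlation, and was left out in some alternatives. The lymph node sample was not left out for its 3' minus 5' value in any of them. Static status was held by 19 of 35 lymph node samples and 7 of 18 aspirates with a known status (Fisher's exact p = 0.387).

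A platform annotation table paired 29254 probe sets with 1 gene symbol, 439 with several and 13231 with none, and 111 were control probe sets. Probe sets with several symbols named no gene. A gene was read from the probe set with the highest mean over all samples, which gave 15115 genes, 8254 of them with more than 1 probe set. A RefSeq gene table (assembly UU_Cfam_GSD_1.0) was used for names and neighbours only, since the genome build behind the array is not given in the sources used here. No level filter was set, since no measure of background was used here.

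Linear models were fitted with limma 3.58.1 in R 4.3.3, with the default eBayes, two-sided tests and Benjamini-Hochberg adjustment over all genes at a threshold of 0.05. The IGHV model held a stratum of 3 levels (lymph node DLBCL, lymph node MZL, aspirate) over 53 samples, and the interaction model added the product of status and specimen. Diagnosis was tested over 39 lymph node samples and specimen over 58 samples, without covariates. PFS and OS were set against each gene with a Cox score test stratified by specimen (Breslow ties), with hazard ratios from survival 3.8.3. An indicator of 1 was read as an event, because all 8 dogs with a PFS indicator of 0 had equal PFS and OS times. Groups were compared by log-rank tests with 100000 permutations, within specimen for IGHV status and over all dogs for specimen, or with every assignment where a group had under 10 dogs. The smallest p these permutations can give is 1e-05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

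Before the data were examined, 29 gene lists were fixed from general knowledge: ABC-like and GCB-like DLBCL, NF-kB targets, B-cell receptor signalling, hypermutation, plasma cell, resting B cell, proliferation, MYC targets, T cell, cytotoxic, macrophage, granulocyte, follicular stroma, extracellular matrix, endothelial, smooth muscle, skeletal muscle, adipocyte, erythroid, platelet, epithelial, interferon, MHC class II, immediate early, hypoxia, BCL2 family, ribosomal protein and oxidative phosphorylation genes. Lists were tested with camera at a preset correlation of 0.01, or on the Cox z values for outcome, with adjustment over the 29 lists. That preset takes the genes of a list as nearly independent. For IGHV status the estimated correlation was 0.598 for proliferation and 0.393 for MHC class II genes. Camera p-values at the preset therefore do not measure the spread between dogs for such lists. An estimated correlation and fry, which asks whether a list's genes move on balance in one direction, were alternatives; fry was run for the linear models only. Some genes stood in more than 1 list, such as CAV1 in the plasma cell and endothelial lists.

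The rule for named genes was also fixed beforehand. It took up to 10 genes each way past the threshold with 1 symbol, with the same sign in both specimens for IGHV status and outcome, and no LOC symbol, or else the 10 with the smallest p. It added up to 4 members of each list past the threshold and 10 preset genes, of which 3 had no probe set named here.

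Scripts were tested on simulated data with 100 changed genes per size among 15115. At a difference of 1 on the log2 scale, 99% were recovered for IGHV status, 92% for diagnosis, 96% for specimen and 84% for the interaction. At 2 these were 100%, 98%, 100% and 97%. Unchanged genes made up 13 of 212 calls for IGHV status, 6 of 196 for diagnosis, 11 of 207 for specimen and 5 of 186 for the interaction. Noise was drawn independently for each gene, without correlation between genes. Smaller differences were not simulated, so these values do not bear on them. A gene correlating at 0.5 with the survival score was recovered in 62% of cases for PFS and 68% for OS. Alternatives changed the probe sets, the normalization, the test, covariates for RNA integrity and for other cells, the strata or the samples, and some changed 2 choices together. An earlier version of the integrity covariate used 1 arbitrary pair of control probe sets per gene; its counts had been seen before all control probe sets replaced it, and both versions are reported.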

Results

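RNA from B-cell lymphomas of 58 pet dogs, sampled before treatment, was measured on Affymetrix canine arrays, 1 array per dog. Tissue came from lymph node in 39 dogs and from fine needle aspirates in 19 dogs. The lymph node tumours were 32 diffuse large B-cell lymphomas (DLBCL, an aggressive tumour of large B cells) and 7 marginal zone lymphomas (MZL, a tumour of marginal zone B cells), and the diagnosis of the 19 aspirates was unknown. The labels also gave the mutation status of the immunoglobulin heavy chain variable gene (IGHV), which was static in 26 dogs, ongoing in 27 dogs and ND, left unexplained by the labels, in 5 dogs. A progression-free survival (PFS) time was given for 55 dogs, with 47 events, and an overall survival (OS) time for 56 dogs, with 41 events. Array medians ran from 7.08 to 7.20 on the log2 scale, and the number of arrays limited the precision.

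IGHV status was compared because ongoing mutation of the antibody gene is a trait of germinal centre B cells, and human DLBCL is divided by its likeness to those cells. Genes of MHC class II presentation, which shows peptides to helper T cells, were lower as a group in static than in ongoing samples, with a median difference of -0.25 (log2) and 10 of 13 members lower (adjusted p = 0.564 with an estimated correlation). That median was -0.41 in lymph node alone and -0.00478 in aspirates alone. DLA-DOA, a modulator of peptide loading, had a level of 11.73 ± 0.64 (SD, n = 26) in static and 12.32 ± 0.33 (n = 27) in ongoing samples, a fold of 0.669. DLA-DMA, a chain of the class II peptide exchange factor, differed by -0.58 ± 0.18 (SE) and the class II chain gene DLA-DQB1 by -0.55 ± 0.20. Cell cycle and DNA replication genes were higher as a group in static samples, with 36 of 38 members higher and a median of 0.26 (0.094 in lymph node and 0.55 in aspirates; adjusted p = 0.564 with an estimated correlation). The spindle assembly factor TPX2 had a fold of 1.44, the cyclin genes CCNA2 and CCNE1 1.46 and 1.22, and the mitotic motor gene KIF11 1.48. GPNMB, a glycoprotein gene of macrophages, had a fold of 1.91 (8.74 ± 0.89 against 7.73 ± 0.78).

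No single gene passed the threshold for IGHV status: limma called 0 of 15115 genes, with 1077 at an unadjusted p under 0.05, and the rank-sum test called 0, with 1002. Chance gives 755.8 at that level in each test of all genes, and lymph node alone gave 339 and aspirates alone 2138. The smallest adjusted p in limma was 0.670, shared by DLA-DOA, GPNMB, the cytoskeletal scaffold gene IQGAP1 (0.39 ± 0.10) and the single-stranded DNA-binding gene SSBP4 (-0.50 ± 0.13). PDLIM2 (-0.40), WASHC4 (0.57), TMEM150A (-0.21), ERCC8 (0.35), TSC22D4 (-0.24) and CLDN12 (0.14) completed the 10 genes with the smallest p, and TPX2, further down, had the same adjusted p. Adjusted over the list alone, 8 members of the MHC class II list fell and 7 members of the proliferation list rose, against 0 of each over all genes. The camera test gave the MHC class II list an adjusted p of 1.38e-06 and the proliferation list 9.65e-16; both had an adjusted p = 0.564 with an estimated correlation. Each specimen was also tested alone. In lymph node the MHC class II median was -0.41, with an adjusted p of 5.50e-14 (adjusted p = 0.0347 with an estimated correlation), and the proliferation median 0.094, with 0.00491 (adjusted p = 0.691 with an estimated correlation). In aspirates the MHC class II median was -0.00478 (adjusted p = 0.830) and the proliferation median 0.55, with 7.07e-19 (adjusted p = 0.516 with an estimated correlation).

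Genes of ribosome biogenesis and metabolism known as MYC targets were also higher as a group in static samples, with 24 of 28 members higher and a median of 0.10 (adjusted p = 5.30e-05; adjusted p = 0.564 with an estimated correlation). The MYC target median was 0.00665 in lymph node (adjusted p = 0.646) and 0.21 in aspirates (8.95e-08; adjusted p = 0.516 with an estimated correlation). Among them were the transferrin receptor gene TFRC (0.50 ± 0.20), the purine synthesis gene PPAT (0.56 ± 0.25), the amino acid transporter gene SLC7A5 (0.15) and the chaperone gene HSPD1 (0.12). The hypermutation and class switch list had 16 of 22 members higher, with the exonuclease gene EXO1 at 0.43 ± 0.16, APEX2 at 0.24, the translesion polymerase gene POLH at 0.31 and RPA2 at 0.26 (adjusted p = 0.0227; adjusted p = 0.564 with an estimated correlation). The hypermutation median was 0.052 in lymph node (adjusted p = 0.272) and 0.11 in aspirates (adjusted p = 0.0581). T lymphocyte markers were lower as a group, in 21 of 25 members, among them GATA3 (-0.27 ± 0.089), CD7 (-0.26), CD5 (-0.17) and the inhibitory receptor gene CTLA4 (-0.35; adjusted p = 0.000377; adjusted p = 0.564 with an estimated correlation). The T-cell median was -0.068 in lymph node (0.0463; adjusted p = 0.636 with an estimated correlation) and -0.22 in aspirates (0.00179; adjusted p = 0.932 with an estimated correlation). Ribosomal protein genes were lower in 44 of 55 members, with small differences such as RPLP2 (-0.074), RPL34 (-0.075), RPS21 (-0.11) and RPS15 (-0.10), and an adjusted p of 6.90e-05 (adjusted p = 0.713 with an estimated correlation). The ribosomal median was -0.028 in lymph node (0.00355; adjusted p = 0.636 with an estimated correlation) and -0.051 in aspirates (0.0171; adjusted p = 0.943 with an estimated correlation). Interferon-induced genes were lower in 21 of 24 members, including the peptide transporter gene TAP1 (-0.17), IFI35 (-0.27), PSMB8 (-0.14) and IRF9 (-0.21; adjusted p = 0.0458; adjusted p = 0.817 with an estimated correlation). The interferon median was -0.21 in lymph node (5.87e-05; adjusted p = 0.454 with an estimated correlation) and turned to 0.057 in aspirates, with 12 of 24 members higher (adjusted p = 0.830). In lymph node DLBCL alone SLC7A5 (-0.0063), POLH (-0.039) and RPA2 (-0.044) turned direction, as did RPL34 with means of probe sets (0.032), and 1 static aspirate stood apart for each of POLH, RPS21, IFI35 and PSMB8. None of these 5 lists had a member past the threshold over all genes or adjusted over the list alone. Without 2 aspirate arrays that correlated least with the others, the adjusted p was 0.120 for hypermutation and 0.232 for interferon, while resting B-cell (0.0135) and granulocyte genes (0.0135) were lower and macrophage markers (0.0103) higher as groups. Resting B-cell genes then had an adjusted p = 0.357 with an estimated correlation, and granulocyte and macrophage markers an adjusted p = 0.484 with an estimated correlation. Genes at an unadjusted p under 0.05 numbered 622 without these arrays, against 755.8 expected by chance.

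The other lists did not pass for IGHV status over both specimens. Their medians were -0.019 for ABC-like DLBCL genes, -0.00778 for GCB-like DLBCL genes, -0.011 for NF-kB targets, -0.017 for B-cell receptor signalling, -0.035 for plasma cell genes and -0.055 for resting B-cell genes. Cytotoxic cell markers had a median of -0.00345, macrophage markers 0.034, granulocyte markers -0.044, follicular stroma -0.083, extracellular matrix genes 0.00824, endothelial markers -0.038 and smooth muscle markers -0.063. Skeletal muscle, adipocyte, erythroid, platelet and epithelial markers had medians of -0.014, -0.00728, -0.023, -0.037 and -0.00980. Immediate early genes had a median of -0.033, hypoxia genes 0.024, BCL2 family genes -0.032 and oxidative phosphorylation genes -0.033. Adjusted over the list alone, 1 macrophage marker rose and 1 endothelial marker fell. The germinal centre regulator BCL6 differed by -0.33 ± 0.22 (SE), the germinal centre surface marker MME by -0.17 ± 0.090, the B-cell receptor gene CD79A by -0.48 ± 0.27 and the B-cell antigen gene MS4A1 by -0.16 ± 0.27. CD3E, CD14 and COL1A1, markers of T cells, monocytes and fibroblasts, differed by -0.12, 0.046 and -0.18; COL1A1 turned in lymph node alone (0.14) and MS4A1 in aspirates alone (0.34).

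Some of these other lists passed within 1 specimen. In lymph node, resting B-cell genes (median -0.11, adjusted p = 0.00163), NF-kB targets (-0.083, 0.0160), B-cell receptor signalling (-0.065, 0.0220) and granulocyte markers (-0.078, 0.0220) were lower in static samples. So were ABC-like (-0.073), GCB-like (-0.039) and plasma cell genes (-0.050), each with 0.0463, and macrophage markers (0.071, 0.00128) and matrix genes (0.060, 0.0220) were higher. Resting B-cell genes had an adjusted p = 0.0532 with an estimated correlation, GCB-like genes an adjusted p = 0.138 with an estimated correlation, ABC-like genes an adjusted p = 0.401 with an estimated correlation and matrix genes an adjusted p = 0.636 with an estimated correlation. The other 5 of these lists had an adjusted p = 0.452 with an estimated correlation. All 9 medians turned sign in aspirates, where none passed: 0.00141 for resting B-cell genes, 0.035 for NF-kB targets, 0.059 for B-cell receptor signalling, 0.032 for granulocyte markers, 0.092 for ABC-like, 8.48e-05 for GCB-like and 0.027 for plasma cell genes, -0.031 for macrophage markers and -0.096 for matrix genes. In aspirates, endothelial (-0.14, 0.00422; adjusted p = 0.938 with an estimated correlation) and smooth muscle markers (-0.14, 0.0189; adjusted p = 0.56845 with an estimated correlation) were lower, against 0.00828 (0.480) and 0.00375 (0.961) in lymph node.

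**Figure D1:**
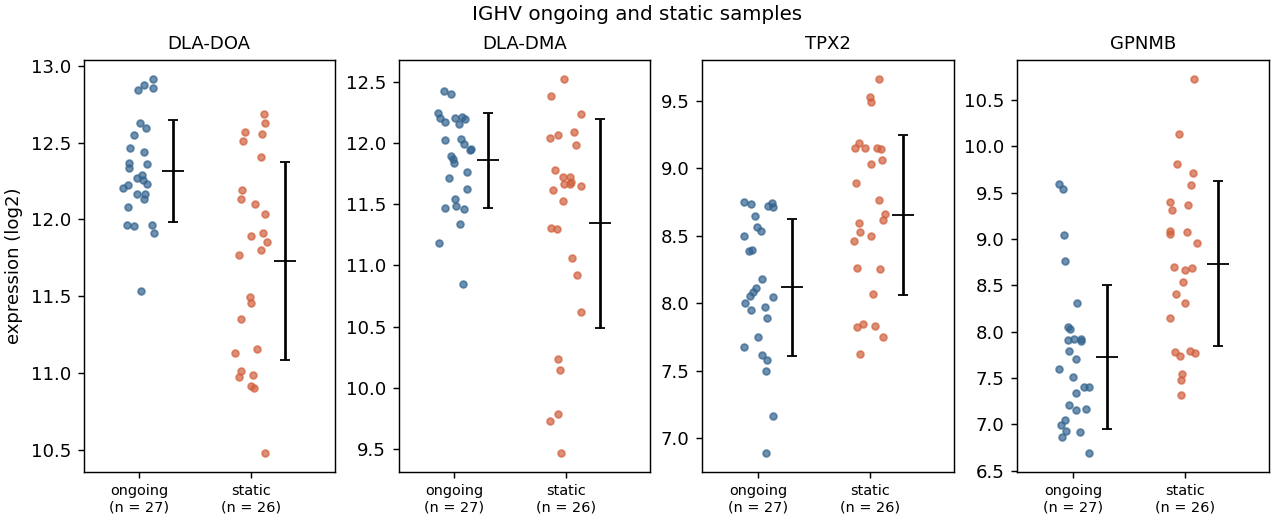
Expression (log2) of 4 genes in ongoing (n = 27) and static (n = 26) samples. Points are dogs, and the bar beside each group is the mean ± SD; the mean of DLA-DOA was 12.32 in ongoing and 11.73 in static samples, and that of GPNMB 7.73 and 8.74.

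A score of ABC-like minus GCB-like genes placed each tumour on the axis that divides human DLBCL. The score was 0.027 ± 0.16 (SD, n = 26) in static and -0.017 ± 0.15 (n = 27) in ongoing samples, a difference within the spread between dogs (two-sided permutation within strata, p = 0.355). Per unit of the score the hazard ratio was 1.80 (95% interval 0.226 to 14.4) for PFS (permutation p = 0.583) and 4.95 (0.504 to 48.5) for OS (permutation p = 0.172). For OS the hazard ratio per unit was 1.99 in lymph node alone (permutation p = 0.610) and 73.8 (0.848 to 6430) in aspirates alone (permutation p = 0.0769). It was 22.1 with medians over genes (permutation p = 0.0536) and 2.54 with genes divided by their SD (permutation p = 0.141). A unit was several times the SD of the score in either group, and its size in SDs differed between ways of scoring. Ratios from different ways of scoring are therefore not on the same scale. With medians the score differed by 0.012 between static and ongoing samples (permutation p = 0.663).

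MZL was compared with DLBCL in lymph node. T lymphocyte markers were higher as a group in MZL, in 21 of 25 members, with a median of 0.17 (adjusted p = 0.225 with an estimated correlation). The T-cell signalling adaptor gene SH2D1A had a level of 7.72 ± 0.89 (SD, n = 7) in MZL and 6.92 ± 0.57 (n = 32) in DLBCL, a fold of 1.73, and CTLA4 had a fold of 1.65, CD7 1.37 and CD8B 1.35. Cytotoxic cell markers were higher in 12 of 15 members, with the killer cell receptor gene KLRD1 at 0.69 ± 0.37 (SE), EOMES at 0.45, the granzyme gene GZMK at 0.70 and the chemokine gene CCL5 at 0.67 (adjusted p = 0.893 with an estimated correlation). TOX, a nuclear factor of T-cell development, had a fold of 3.08 (7.59 ± 1.56 against 5.96 ± 1.09, SD), and the calpain gene CAPN2 a fold of 0.469. TOX also stands in the GCB-like DLBCL list, and the cells behind its difference were not tested. Of that list 1 member rose adjusted over the list alone, while the list as a whole did not pass (camera adjusted p = 0.672).

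Ribosomal protein genes were higher in 51 of 55 members in MZL, with a median of 0.044 (RPL24 0.10, RPL7A 0.077, RPL9 0.075, RPL12 0.14; adjusted p = 0.590 with an estimated correlation). Oxidative phosphorylation genes were higher in 48 of 68 members (COX7A2L 0.15, ATP5MC3 0.17, NDUFB6 0.13, UQCRH 0.053; adjusted p = 0.893 with an estimated correlation). Proliferation genes were lower in 33 of 38 members, among them the nucleotide reductase gene RRM2 (-0.27) and the kinase gene PBK (-0.29), the replication helicase gene MCM7 (-0.15) and KIF23 (-0.24; adjusted p = 0.893 with an estimated correlation). MYC targets were lower in 25 of 28 members, with MYC at -0.36 ± 0.19 (SE), RRP12 at -0.18, MAT2A at -0.13 and LDHA at -0.083 (adjusted p = 0.893 with an estimated correlation). Granulocyte markers were lower in 12 of 16 members, including the myeloperoxidase gene MPO (-0.39 ± 0.16), CAMP (-0.23), ELANE (-0.13) and LTF (-0.51; adjusted p = 0.893 with an estimated correlation). In camera the adjusted p was 1.26e-12 for ribosomal proteins, 2.78e-10 for T cells, 0.00642 for cytotoxic cells, 0.0164 for granulocytes, 0.0187 for oxidative phosphorylation, 0.0322 for proliferation and 0.0335 for MYC targets. None held otherwise: the T-cell list had an adjusted p = 0.225 with an estimated correlation, the ribosomal list an adjusted p = 0.590 with an estimated correlation, and the other 5 lists an adjusted p = 0.893 with an estimated correlation.

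By limma 0 genes passed between MZL and DLBCL, with 176 at an unadjusted p under 0.05 and every adjusted p at 1.00, and the rank-sum test called 0 genes, with 188. Over all genes and adjusted over the list alone, 0 members of the lists called by camera passed. The 10 genes with the smallest p were TOX, CAPN2, SH2D1A, the NAD synthesis gene NMNAT1 (0.33 ± 0.089, SE), the cholinesterase gene BCHE (0.62), the endoplasmic reticulum chaperone gene DNAJB11 (0.18), the membrane protease gene SPPL2A (0.32), ZFPM2 (0.76), the peptidase gene DPP4 (0.46) and the prostaglandin receptor gene PTGDR (0.46). BCL6 differed by 0.28, MME by -0.061, CD79A by -0.53, MS4A1 by 0.24, CD3E by 0.19, CD14 by 0.037 and COL1A1 by 0.53. MZL status was carried by 7 dogs, of which 4 were ongoing and 1 was static.

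Aspirates were compared with lymph node samples to show what the way of sampling brings. The largest differences were in LOC476825 and LOC100855558, singled out after their values were seen because the naming rule left out such symbols. LOC476825, which lies beside beta-globin cluster genes in the reference gene table, had a level of 9.11 ± 3.49 (SD, n = 19) in aspirates and 4.54 ± 1.08 (n = 39) in lymph node, and rose by 4.57 ± 0.59 (SE); its lymph node level was not set against a measure of background. LOC100855558, a neighbour of the alpha-globin cluster genes HBQ1 and HBM, rose 5.96-fold (12.48 ± 2.02 against 9.91 ± 0.81). ALAS2, the erythroid enzyme gene of haem synthesis, rose 1.52-fold, and GNG11, a G protein subunit gene, rose 2.21-fold.

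Of 15115 genes, 14 rose and 4 fell in aspirates. SNCG, a synuclein gene, rose by 0.73 ± 0.16 (SE), the Hippo pathway coactivator gene WWTR1 by 0.36, UTS2B by 0.28, AZIN2 by 0.24, SLC35C2 by 0.24 and the natural killer receptor gene NCR3 by 0.23. PLEKHH2, RAB11FIP5, UGT2B31 and IRAK2 rose by 0.23, 0.22, 0.21 and 0.16. UTS2B (4.72 in aspirates and 4.44 in lymph node) and UGT2B31 (4.74 and 4.53) had low levels, under the lowest array median of 7.08. Neither was set against a measure of background. C8H14orf28 fell by 0.50, AKAP7, an anchoring protein gene of kinase A, fell by 0.41, DMAC2L fell by 0.38 and the heterochromatin protein gene CBX1 fell by 0.37. The adjusted p in limma ran from 2.87e-06 for LOC476825 to 0.0499 for UGT2B31. The rank-sum test called 0 genes, with 1594 at an unadjusted p under 0.05, and gave LOC476825 an adjusted p of 0.0792. Without the 2 aspirate arrays that correlated least with the others, limma called 10 genes, of which 8 were among the 18: LOC476825, LOC100855558, ALAS2, GNG11, SNCG, PLEKHH2, AKAP7 and CBX1. The other 10 of the 18 lost their call.

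**Figure D2:**
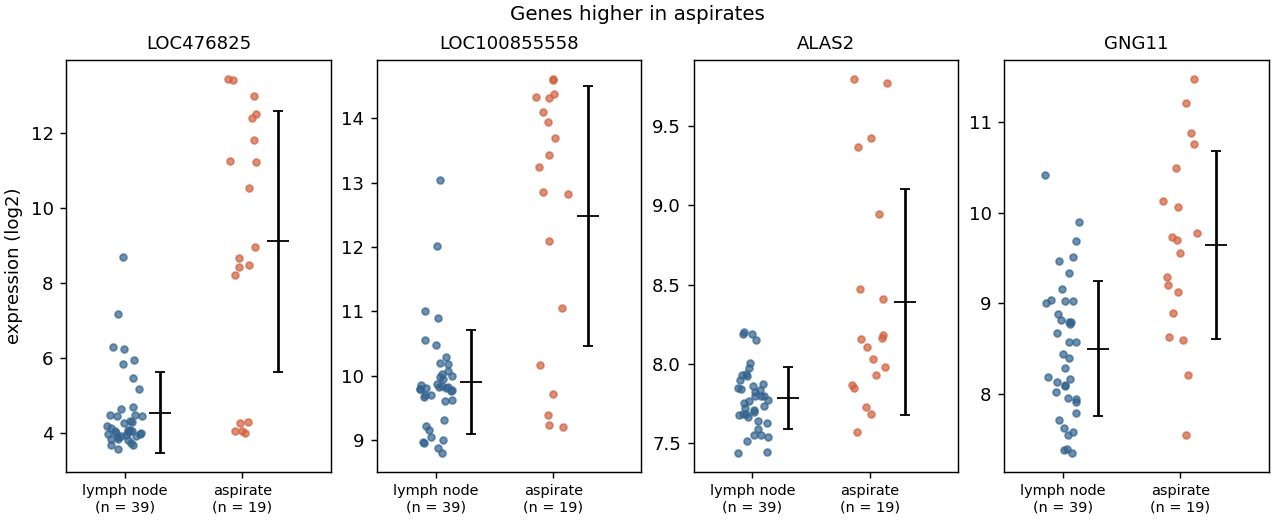
Expression (log2) of 4 genes in lymph node (n = 39) and aspirate (n = 19) samples. Points are dogs and bars are the mean ± SD; the mean of LOC476825 was 4.54 in lymph node and 9.11 in aspirates, where the SD was 3.49.

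Markers of several non-tumour cell types were higher as groups in aspirates, none with an adjusted p under 0.05 with an estimated correlation. T lymphocyte markers were higher in 24 of 25 members (adjusted p = 0.140 with an estimated correlation), with CD28, a costimulatory receptor gene, at 0.34 ± 0.094 (SE), CD6 at 0.22, FOXP3 at 0.12 and CD3E at 0.23, and 7 members rose adjusted over the list alone. Cytotoxic markers were higher in 15 of 15 members (NCR1 0.091, KLRD1 0.56, GZMA 0.40; adjusted p = 0.382 with an estimated correlation). Endothelial markers were higher in 23 of 24 members (adjusted p = 0.140 with an estimated correlation), with the junction gene CDH5 at 0.12, RAMP2 at 0.56, the caveolin gene CAV1 at 0.77 and FLT4 at 0.16, and 7 rose adjusted over the list alone. Smooth muscle (DES 0.12, RGS5 0.15, CALD1 0.57, LMOD1 0.18), extracellular matrix (COL14A1 0.21, COL5A1 0.089, THY1 0.29, SPARC 0.66) and follicular stroma genes (CCL21 0.65, SERPINE2 0.75, CCL19 0.58, VCAM1 0.45) were higher in 10 of 12, 24 of 32 and 11 of 14 members. Smooth muscle had an adjusted p = 0.140 with an estimated correlation, matrix an adjusted p = 0.438 with an estimated correlation and follicular stroma an adjusted p = 0.382 with an estimated correlation. Interferon-induced genes were higher in 23 of 24 members (IRF9 0.29, TAP1 0.13, IRF7 0.48, ISG20 0.59; adjusted p = 0.514 with an estimated correlation), and granulocyte markers in 13 of 16 (PGLYRP1 0.31, S100A9 0.81, CAMP 0.22, S100A8 0.64; adjusted p = 0.382 with an estimated correlation). Plasma cell genes were higher in 12 of 19 members (CREB3L2 0.17, CD27 0.58, XBP1 0.18; adjusted p = 0.382 with an estimated correlation), and erythroid genes in 6 of 8 (HBE1 0.11, EPB42 0.063, HEMGN 0.20; adjusted p = 0.407 with an estimated correlation). Over all genes, 1 cytotoxic member, NCR3, and 1 erythroid member, ALAS2, passed. Some of the markers named here had low levels in lymph node, such as LMOD1 (4.33), RGS5 (5.29), FOXP3 (5.52) and NCR1 (5.53). They were not set against a measure of background.

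Lower as groups in aspirates were ribosomal proteins, in 47 of 55 members (RPS16 -0.10, RPL13A -0.069, RPL9 -0.070, RPS12 -0.037; adjusted p = 0.514 with an estimated correlation), and oxidative phosphorylation, in 56 of 68 (NDUFV3 -0.73 ± 0.23, NDUFA3 -0.22, SDHD -0.16 and the complex I assembly factor gene NDUFAF5 -0.21; adjusted p = 0.632 with an estimated correlation). Proliferation genes were lower in 32 of 38 members (CENPF -0.47, GINS2 -0.22, TYMS -0.18, MCM2 -0.29; adjusted p = 0.632 with an estimated correlation), and hypermutation genes in 15 of 22 (XRCC4 -0.41, RPA3 -0.29, TP53BP1 -0.15, RNF8 -0.14; adjusted p = 0.438 with an estimated correlation). Adjusted p in camera was 7.75e-10 for T cells, 1.30e-08 for endothelium, 7.75e-05 for cytotoxic cells, 0.000158 for smooth muscle, 0.00282 for matrix and for interferon, 0.00670 for granulocytes, 0.0116 for follicular stroma, 0.0210 for erythroid and 0.0379 for plasma cell genes. It was 0.000354 for ribosomal proteins, 0.00515 for oxidative phosphorylation, 0.00552 for proliferation and 0.0483 for hypermutation. T cells, endothelium and smooth muscle had an adjusted p = 0.140 with an estimated correlation, and for the other lists it reached an adjusted p = 0.632 with an estimated correlation. In fry the same 3 lists passed, each with an adjusted p of 0.0271. Without the 2 aspirate arrays that correlated least with the others, the adjusted p in camera was 0.0713 for granulocytes, 0.0988 for erythroid genes, 0.0689 for ribosomal proteins and 0.252 for oxidative phosphorylation, while B-cell receptor signalling (0.0103), MHC class II (0.0112) and hypoxia genes (0.0407) were higher as groups. Of these, B-cell receptor signalling and hypoxia had an adjusted p = 0.291 with an estimated correlation, and MHC class II an adjusted p = 0.415 with an estimated correlation. Preset genes gave 0.13 for BCL6, 0.20 for MME, 0.22 for CD79A, 0.11 for MS4A1, -0.11 for CD14 and 0.39 for COL1A1. Sampling method and a known diagnosis cannot be told apart, since every aspirate had an unknown diagnosis; with lymph node DLBCL alone as the comparison, 6 genes passed.

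**Figure D3:**
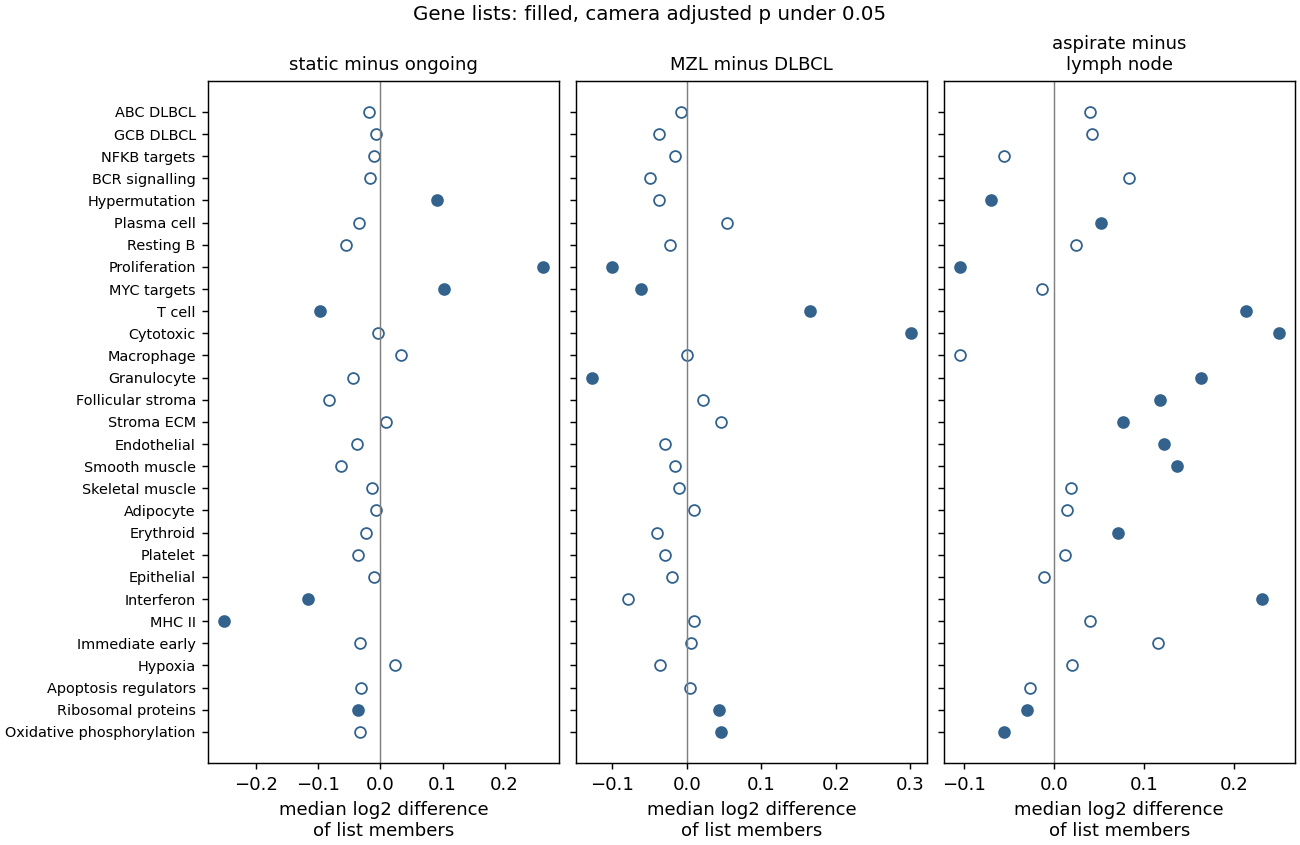
Median log2 difference of the members of each gene list (horizontal axis) in 3 comparisons; filled points have a camera adjusted p under 0.05, and no list had an adjusted p under 0.05 with an estimated correlation. The MHC class II list lies at -0.25 for static minus ongoing, and the T-cell list at 0.17 for MZL minus DLBCL and 0.21 for aspirate minus lymph node.

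The IGHV difference itself was compared between specimens. CLK3, a kinase gene of splicing regulation, had a static minus ongoing difference of 0.11 in lymph node and -0.66 in aspirates, a gap of -0.77 ± 0.12 (SE; limma interaction, adjusted p = 0.000798). ATF7IP2, a chromatin-associated gene, had differences of -0.24 and 0.71, a gap of 0.94 ± 0.18 (adjusted p = 0.0339). ATF7IP2 lost its call without the 2 arrays that correlated least with the others (gap 0.89, adjusted p = 0.132). It also lost it with quantile normalization again (0.93, adjusted p = 0.0526) and with all probe sets (0.94, adjusted p = 0.0967). CLK3 kept its call in each, with gaps of -0.67, -0.82 and -0.77. Proliferation genes had a positive gap as a group, with a median of 0.47 and 37 of 38 members positive (RRM2 0.023 in lymph node and 0.93 in aspirates, CDC6 0.051 and 0.94; adjusted p = 0.419 with an estimated correlation). For MHC class II genes the median gap was 0.33, with DLA-DQA1 at -0.54 in lymph node and 0.39 in aspirates and DLA-DOB at -1.49 and 0.27 (adjusted p = 0.453 with an estimated correlation). MYC targets (LDHA -0.030 and 0.38, NPM1 -0.19 and 0.43) and B-cell receptor signalling genes (RASGRP3 -0.12 and 0.84, BCL10 0.019 and 0.71) had positive gaps as groups (both adjusted p = 0.419 with an estimated correlation). Endothelial (ECSCR 0.26 and -0.26), matrix (FAP 0.10 and -0.16), smooth muscle (MYL9 0.014 and -0.94) and T-cell genes (CD7 -0.093 and -0.58) had negative gaps as groups. Endothelium and smooth muscle had an adjusted p = 0.419 with an estimated correlation, and matrix and T cells an adjusted p = 0.548 with an estimated correlation.

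The interaction had 2 genes past the threshold of 15115, with 1375 at an unadjusted p under 0.05. Camera adjusted p was 2.07e-11 for proliferation, 1.85e-06 for MYC targets, 0.000198 for endothelium, 0.00327 for MHC class II, 0.0123 for B-cell receptor signalling and matrix, and 0.0181 for T cells and smooth muscle. Proliferation, MYC targets, endothelium, B-cell receptor signalling and smooth muscle had an adjusted p = 0.419 with an estimated correlation, MHC class II an adjusted p = 0.453 with an estimated correlation, and matrix and T cells an adjusted p = 0.548 with an estimated correlation. Aspirates alone gave 6 genes for IGHV status, singled out here after their values were seen: ASB7 (0.56) and PRKAB2 (0.49) rose in static samples, and CLK3, LOC486404 (-1.27), the transcription factor gene TFAP2B (-3.47) and ZBTB4 (-1.03) fell. Only 7 static aspirates entered, and without the 2 arrays that correlated least with the others 1 gene, CLK3, passed the interaction. In that setting interferon-induced genes also had a positive gap as a group, with a median of 0.67, 22 of 24 members positive and an adjusted p of 4.07e-05 (adjusted p = 0.393 with an estimated correlation). NF-kB targets had a median gap of 0.17 there, with 0.0206 (adjusted p = 0.405 with an estimated correlation).

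Outcome was compared between IGHV groups. Static dogs had a median PFS of 202 (95% interval 142 to 288; the labels give no time unit, and indicator 1 was read as an event) and ongoing dogs 317 (193 to 523), with 23 events in 25 dogs and 21 in 27. The hazard ratio of static to ongoing was 1.98 (1.06 to 3.68), and the log-rank test stratified by specimen gave a two-sided permutation p of 0.0311. That p was not adjusted over the other comparisons of outcome between groups, which covered OS, diagnosis and specimen. None of those had a permutation p under 0.05 in its main test. In lymph node the hazard ratio was 2.37 (permutation p = 0.0276), and in aspirates 1.42 (exact p = 0.539). The Peto-Peto test, which weights early events, gave a permutation p of 0.0888. In lymph node DLBCL alone, with 17 static and 12 ongoing dogs, the hazard ratio was 2.00 (0.863 to 4.63, permutation p = 0.0977). Median OS was 240 (192 to 505) in static and 515 in ongoing dogs, with a hazard ratio of 1.57 (0.806 to 3.07; permutation p = 0.189). For OS the hazard ratio was 2.21 in lymph node (permutation p = 0.0676) and turned to 0.821 in aspirates (exact p = 0.763).

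**Figure D4:**
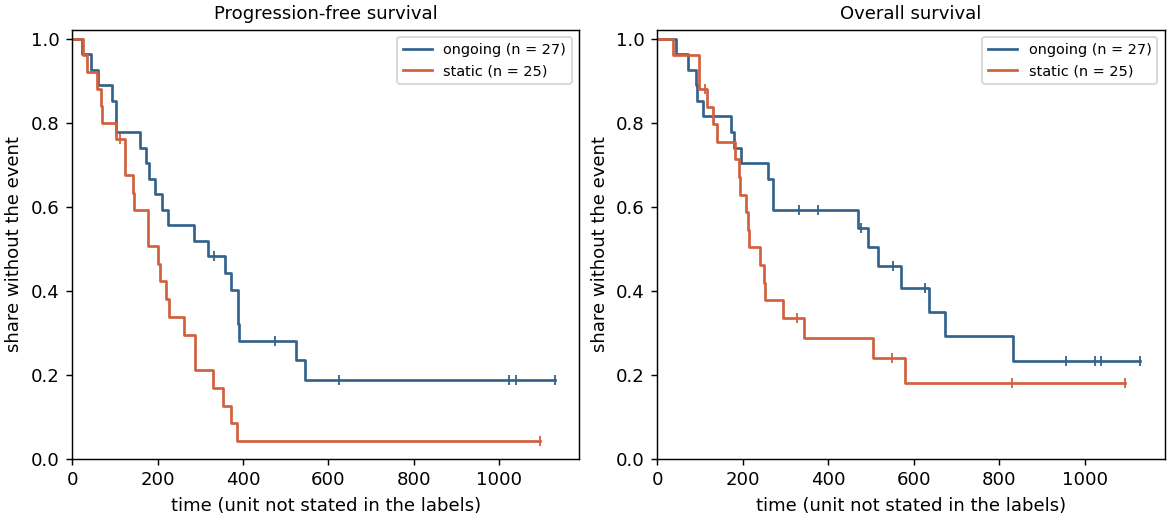
Kaplan-Meier curves of PFS (left) and OS (right) for ongoing and static dogs; the vertical axis is the share of dogs without the event, the horizontal axis is time in the unstated unit of the labels, and ticks are censored dogs. Median PFS was 202 in 25 static and 317 in 27 ongoing dogs.

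Diagnosis and specimen did not separate outcome past the threshold. MZL dogs had a median PFS of 285.5 and DLBCL dogs 178, with a hazard ratio of 0.578 (0.201 to 1.66; exact permutation p = 0.267), and median OS of 470 and 240, with a hazard ratio of 0.649 (exact permutation p = 0.337). Aspirate dogs had a median PFS of 270 and lymph node dogs 202 (hazard ratio 0.649, permutation p = 0.144), and median OS of 367 and 252 (hazard ratio 0.550, permutation p = 0.0764).

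Gene levels were then set against outcome. Per log2 unit, the kynurenine pathway enzyme gene KMO had a hazard ratio of 0.480 (95% interval 0.324 to 0.713) for PFS, the cyclin gene CCND3 2.46 (1.54 to 3.93), the neutrophil granule gene BPI 4.62, IGSF9 2.64, the galectin gene LGALS3 1.70 and the lymphocyte egress receptor gene S1PR1 0.660. SRP19, PDE11A, the vascular receptor gene FLT1 and GRB7 had hazard ratios of 0.00870, 10.00, 0.117 and 2.46. Matrix genes ran with earlier progression as a group, in 26 of 32 members (TIMP1 1.62, FN1 1.38, CTSK 1.82, LUM 1.64; adjusted p = 0.577 with an estimated correlation), as did macrophage markers in 20 of 28 (SLC11A1 4.09, GPNMB 1.60, MSR1 1.43, VSIG4 2.21; adjusted p = 0.577 with an estimated correlation) and proliferation genes in 37 of 38 (PBK 1.74, GINS2 2.41, RRM2 1.63, CDC6 1.61; adjusted p = 0.964 with an estimated correlation). MHC class II genes ran the other way in 10 of 13 members (DLA-DQB1 0.639, DLA-DQA1 0.583, HLA-DRB1 0.451, DLA-DMA 0.657). In camera the adjusted p was 3.97e-06 for proliferation, 7.32e-06 for matrix, 1.89e-05 for MHC class II and 0.00139 for macrophages; proliferation had an adjusted p = 0.964 with an estimated correlation, and the other 3 lists an adjusted p = 0.577 with an estimated correlation. Adjusted over the list alone, 2 macrophage markers passed with earlier progression, and 1 resting B-cell gene and 1 endothelial marker passed the other way. The Cox score test called 0 genes over all genes, with 428 at an unadjusted p under 0.05, and the test on ranks called 0, with 447. BCL6, MME, CD79A, MS4A1, CD3E, CD14 and COL1A1 had hazard ratios of 0.776, 1.33, 0.941, 0.931, 0.583, 2.00 and 1.16.

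For OS, DDX43, a helicase gene usually active in testis, was the 1 gene past the threshold, with a hazard ratio of 3.97 (1.81 to 8.67) per log2 unit and an adjusted p of 0.0111. The gene falls outside the naming rule and was chosen after its values were seen: its score z was 6.18 in lymph node and -1.84 in aspirates. Without the 2 dogs with the highest level the score z was 1.62, and on ranks the adjusted p was 1.00. Next came the olfactory receptor gene OR56A4B, HDGFL3 (hazard ratio 0.402), the histone messenger binding gene SLBP (16.3), SUPT3H (0.167), CLTB (0.114), IGSF9 (2.61), CAMSAP2 (0.113), the germinal centre signalling gene RGS13 (1.35), GALNT3 (0.627) and GRB7 (2.63), none past the threshold. Of 15115 genes, 603 had an unadjusted p under 0.05, and the test on ranks called 0 genes, with 627.

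Higher levels went with earlier death for proliferation genes in 36 of 38 members (PBK 1.83, GINS2 2.52, CENPF 1.54, CDC6 1.70; adjusted p = 0.651 with an estimated correlation), matrix genes in 27 of 32 (TIMP1 1.57, FN1 1.44, SPARC 1.30, COL1A2 1.30; adjusted p = 0.430 with an estimated correlation) and macrophage markers in 22 of 28 (SLC11A1 3.62, MSR1 1.47, TYROBP 1.495, GPNMB 1.35; adjusted p = 0.430 with an estimated correlation). The same direction held for cytotoxic markers in 13 of 15 members (GZMB 1.20, CCL5 1.24, GZMA 1.47, PRF1 2.69; adjusted p = 0.651 with an estimated correlation) and plasma cell genes in 16 of 19 (SEL1L 3.80, CAV1 1.36, PRDM1 3.25, DERL3 1.90; adjusted p = 0.430 with an estimated correlation). MHC class II genes had lower hazard with higher level in 11 of 13 members (HLA-DRB1 0.455, DLA-DQB1 0.673, DLA-DMA 0.648, DLA-DQA1 0.616; adjusted p = 0.651 with an estimated correlation). Camera adjusted p was 2.23e-07 for proliferation, 1.19e-06 for matrix, 0.000657 for macrophages, 0.00452 for cytotoxic, and 0.00575 for plasma cell and MHC class II genes. Matrix, macrophage and plasma cell genes had an adjusted p = 0.430 with an estimated correlation, and proliferation, cytotoxic and MHC class II genes an adjusted p = 0.651 with an estimated correlation. Over all genes and adjusted over the list alone, 0 members of these 6 lists passed. BCL6, MME, CD79A, MS4A1, CD3E, CD14 and COL1A1 had hazard ratios of 0.703, 1.41, 1.07, 1.31, 0.460, 2.09 and 1.19.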

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

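The Dixon test and the interaction test were planned; the lists and genes weighed here were picked after their results were seen, and so were the adjustment over 29 lists and the bootstrap intervals used to judge them, which made the readings more cautious.

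Single samples stood apart in 6 of 88 gene and group pairs of 7 samples, where chance gives about 1 in 20, or 4.4. Among static aspirates, 1 sample had a POLH level of 9.63 against 8.79 in the nearest sample, a gap of 0.618 of the group's range. Low samples in that group had gaps of 0.743 for IFI35, 0.638 for PSMB8, 0.704 for DLA-DQB1 and 0.682 for RPS21. In MZL the lowest SPPL2A sample had a gap of 0.6245, at 9.61 against 9.93.

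The static minus ongoing difference differed between aspirates and lymph node for ATF7IP2 by 0.94 and for CLK3 by -0.77. List medians differed by 0.12 for B-cell receptor signalling, 0.47 for proliferation, 0.19 for MYC targets, -0.18 for T cells, -0.21 for extracellular matrix, -0.14 for endothelium, -0.13 for smooth muscle and 0.33 for MHC class II. Of these, T cells and matrix had an adjusted p = 0.548 with an estimated correlation, MHC class II an adjusted p = 0.453 with an estimated correlation and the other 5 lists an adjusted p = 0.419 with an estimated correlation. At least as many genes came from 4 of 100 regroupings of the samples, the real one included, narrowly under the bound of 5 set beforehand. That bound made no allowance for the other comparisons tested in this way. The highest other regrouping gave 903 genes, so chance stays open for the count of 2. Those 903 genes may point to a structure of the samples. Neither such a structure nor another explanation of these differences was tested.

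In static samples the proliferation list was higher and the MHC class II list lower (both adjusted p = 0.564 with an estimated correlation). The MHC class II median was -0.41 in lymph node and -0.00478 in aspirates. The fits below pooled both specimens and held no measure of B-cell content. For MHC class II, adding T-cell, macrophage and matrix means kept 88.6% of the score difference (bootstrap interval 55.8 to 129) and adding the 3' minus 5' value kept 104% (84.9 to 134), which argues against those cells and RNA integrity as the whole cause. For proliferation the same covariates kept 82.9% (18.8 to 120) and 98.2% (23.8 to 103), past the bound set beforehand but with intervals too wide to exclude either. A chance difference between dogs stays open for both: permutation p was 0.0277 for proliferation and 0.00479 for MHC class II, under the bound of 0.05 set beforehand, but that bound left out that the lists were picked out of 29, over which the adjusted p was 0.372 and 0.139. A biological difference tied to IGHV status may underlie either list and stays equally open.

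LOC476825 and LOC100855558 were higher in aspirates by a mean of 3.57 (log2). A few deviating arrays are argued against, since 14 of 19 aspirates lay above the 90th percentile of lymph node samples. The largest difference among 63 spiked control probe sets was 0.129, under the bound set beforehand for an array-wide labelling difference. These probe sets were read after normalization between arrays, which can remove such a difference, so they cannot decide on it. Blood in the aspirates may be the source: the mean of these genes and that of ALAS2 and SLC4A1, a red cell membrane gene, correlated within aspirates with a Spearman rho of 0.386 (permutation p = 0.103; 0.128 over 5 relations) and a Pearson r of 0.491 (permutation p = 0.0322; 0.0537 over 5 relations; 0.535 without the 2 farthest samples). That rho lies between the bounds set beforehand, so blood cannot be told apart from other origins here, a difference of the tumours themselves among them, which was not tested.

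For DDX43 and OS, 2 dogs had levels of 6.83 and 6.12, against a median of 3.86, and OS times of 93 and 71. A few dogs with high values may account for the call, since without them the score z was 1.62; leaving out 1 dog at a time gave z from 3.80 to 5.42. Chance was not excluded for the count of 1 gene, which 12 of 100 regroupings reached, with up to 3 genes in another. No biological explanation was tested.

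For the count of 18 genes between aspirates and lymph node chance is argued against: no other of 100 regroupings gave more than 5 genes, and 1, the real one, gave as many. The regrouping test concerns the count and not each gene. By rank-sum test 0 genes passed, and 8 of the 18 kept their call without the 2 arrays of lowest correlation. For IGHV status, diagnosis and PFS the regrouping test decides nothing about chance, since any regrouping reaches the count of 0 genes, as 100 of 100 did. The highest other counts were 1, 564 and 1. The 564 for diagnosis may point to a structure of the samples, which was not tested.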

How the results depend on the processing

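Alternatives without the 2 arrays of lowest correlation (both aspirates, so MZL against DLBCL was not altered), lists within each specimen, an estimated correlation in these settings, and the earlier integrity covariate were chosen after seeing the data; the others were planned. Of the values for comparisons, 97 stayed the same under an alternative, 51 moved, 3 lost a call and 1 turned. Of those for named genes and for the lists past the threshold, 3815 kept their direction and side of the threshold, 155 lost a call, 11 gained a call and 29 turned. Where a value changed, the cause was not tested unless the alternative tests fewer samples or genes. Aspirate against lymph node gave 18 genes, and 6 among genes in the upper part of mean level, 37 with quantile normalization again, 41 with arrays centred on their medians, 137 with all probe sets, 58 with means of a gene's probe sets, 78 with array weights, 0 by rank-sum test, 41 with the 3' minus 5' covariate, 10 (7 of the 18) with T-cell, macrophage and matrix covariates, 6 against lymph node DLBCL only, 10 (8 of the 18) without the 2 arrays, 101 at an adjusted p of 0.1 and 5 with a 1.5-fold minimum. The earlier integrity covariate gave 22. IGHV status gave 6 genes in aspirates only. The interaction gave 1 gene with quantile normalization again, 1 with all probe sets, 5 with array weights and 1 without the 2 arrays. PFS gave 1 gene with all probe sets, 1 with means of probe sets and 1 in lymph node samples only. OS gave 0 in the upper part of mean level, 2 with quantile normalization again, 2 with all probe sets, 2 with means of probe sets, 0 without strata, 0 with 3 strata, 3 in lymph node samples only, 0 in aspirates only, 0 with IGHV status as a further stratum, 0 on ranks and 0 with the cell covariates. Gene lists passed 36 times over the linear models, 0 times with an estimated correlation (0 lists for IGHV status, 0 for diagnosis, 0 for specimen, 0 for the interaction, 0 for PFS, 0 for OS) and 3 times with fry (0 for IGHV status, 0 for diagnosis, 3 for specimen, 0 for the interaction). For IGHV status 7 lists passed, and 14 in lymph node samples only; with an estimated correlation 1 passed in lymph node samples only, 0 in aspirates only and 0 in any comparison without the 2 arrays.

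PFS by IGHV status, with a hazard ratio of 1.98 in the main test, lost its call in aspirates only (exact p = 0.539, hazard ratio 1.42). It also lost it by the Peto-Peto test (permutation p = 0.0888) and in lymph node DLBCL only (permutation p = 0.0977, hazard ratio 2.00). OS by IGHV status turned its direction in aspirates only (exact p = 0.763, hazard ratio 0.821). The genes that turned, apart from DDX43, passed in neither setting. With the cell covariates BCL6 (-0.13) and COL1A1 (-0.10) turned for specimen, CD14 (-0.039) and COL1A1 (-0.0078) for diagnosis, CD14 (score z -0.15) and MME (-1.21) for OS, and CD14 (-0.063), COL1A1 (-0.41), MME (-1.48) and MS4A1 (0.33) for PFS. With array weights CD14 (0.00666) and CD79A (-0.039) turned for the interaction and COL1A1 (0.0012) for IGHV status. CD14 turned for the interaction without the 2 arrays (0.014), and for diagnosis without MZL replicate 4, with values from -0.014 to 0.084 as each MZL sample was left out, and COL1A1 for diagnosis in ongoing samples only (-0.16). CD79A turned for the interaction in lymph node DLBCL only (-0.015) and for OS in aspirates only (-0.070). COL1A1 turned for IGHV status in lymph node samples only (0.14) and MS4A1 in aspirates only (0.34). For PFS without strata MME (-0.17) and MS4A1 (0.070) turned, and MS4A1 in aspirates only (0.56). POLH (-0.039), RPA2 (-0.044) and SLC7A5 (-0.0063) turned for IGHV status in lymph node DLBCL only, and RPL34 with means of probe sets (0.032). DDX43 turned for OS in aspirates only (-1.84). The interferon list, which passed over both specimens, turned for IGHV status in aspirates only (adjusted p = 0.830).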

Other observations

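The tests in this part were chosen after the data had been seen; what the last pair of tests would show was set down before their values were computed.

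The axis that separated the 58 dogs most, the first principal component with 12.9% of the variance, had these named genes among the 10 at each end. At its high end stood the collagen gene COL1A1 (7.31 ± 1.46, SD, n = 58), the protease inhibitor gene TIMP1 (8.00 ± 1.13), the chemoattractant gene RARRES2 (10.21 ± 1.53), the metallothionein gene MT2A (8.79 ± 1.45) and NFIA (8.42 ± 1.71), and at its low end the Polycomb gene SUZ12 (9.19 ± 1.14), PPAT (8.80 ± 0.89), the lactate transporter gene SLC16A1 (7.46 ± 0.89) and the kinase inhibitor gene PKIA (8.42 ± 2.54). Among the 29 list scores, hypermutation correlated with this axis at r = -0.753 (permutation p = 1e-05, the smallest the permutations can give, adjusted 4.14e-05) and rho = -0.602 (permutation p = 2e-05, adjusted 6.44e-05), with r = -0.716 without the 2 farthest dogs, -0.674 in lymph node and -0.898 in aspirates. Platelet markers correlated at r = 0.722 (permutation p = 1e-05, adjusted 4.14e-05) and rho = 0.740 (permutation p = 1e-05, adjusted 5.80e-05), with r = 0.700 without the 2 farthest dogs, 0.755 in lymph node and 0.654 in aspirates. The axis was not particular to these 2 lists. Further lists ran with it, each with a Pearson permutation p adjusted to 0.000129 or less: skeletal muscle (r = 0.645, rho = 0.5684), oxidative phosphorylation (0.611 and 0.406), endothelium (0.581 and 0.619), epithelium (0.569 and 0.534), smooth muscle (0.567 and 0.641), erythroid genes (0.527 and 0.554) and B-cell receptor signalling (-0.590 and -0.584). MHC class II genes correlated at r = -0.00715 (permutation p = 0.957) and rho = -0.116 (permutation p = 0.384, adjusted 0.464). The axis was computed from the same genes, so these relations describe it and are not independent of it. The axis also ran with array quality. The interquartile range of an array's values correlated with it at r = -0.719 (permutation p = 1e-05, adjusted 3e-05) and rho = -0.729 (permutation p = 1e-05, adjusted 3e-05), with r = -0.734 without the 2 farthest dogs, -0.747 in lymph node and -0.722 in aspirates. The 3' minus 5' value correlated at r = 0.422 (permutation p = 0.00278, adjusted 0.00417) and rho = 0.4999 (permutation p = 0.00016, adjusted 0.00024), with r = 0.490 without the 2 farthest dogs, 0.281 in lymph node and 0.726 in aspirates. The mean correlation with the other arrays gave r = 0.0326 (permutation p = 0.804) and rho = -0.0580 (permutation p = 0.664). Array quality and the tumours cannot be told apart on this axis.

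Interferon-induced genes varied most between dogs among the list scores, with an SD of 0.732 (log2), followed by cytotoxic markers (0.5676), proliferation (0.399) and MHC class II (0.398), and ribosomal proteins varied least (0.0831).

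A hypothesis was that tumours with more proliferation carry less MHC class II RNA. Both lists had already been seen to differ in opposite directions by IGHV status in these dogs. Status was not held fixed in the correlation, so it is not separate evidence. Over 58 dogs the scores correlated with a Spearman rho of -0.366 (permutation p = 0.00464; 0.0116 over 5 relations) and a Pearson r of -0.370 (permutation p = 0.00443, adjusted 0.0119), and r was -0.422 without the 2 farthest dogs. Within lymph node rho was -0.481 (permutation p = 0.00253, adjusted 0.0116) and within aspirates -0.191 (permutation p = 0.431); the difference between specimens was not tested. A further hypothesis, that dogs with a higher proliferation score progress earlier, was left undecided: the hazard ratio per unit was 1.63 (0.720 to 3.71; permutation p = 0.240, n = 55), and for OS it was 1.77 (permutation p = 0.197).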
